A study of Hymenochirus boettgeri with 8 samples.

How the data were processed

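RNA-seq libraries of poly-A RNA from 8 samples of whole eggs, embryos or tadpoles of wild-type Hymenochirus boettgeri were analysed, 2 for each of 4 stages: unfertilized egg, 8-cell stage, NF stage 26 and swimming tadpole. Per the labels' protocols, RNA was extracted with TRIzol and column-purified, and strand-specific Illumina libraries were made after poly-A capture. Stages and replicate numbers were taken from the source names of the samples, and each column of the table was matched to its sample by the sample's title.

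The deposited values are TPM, a share of all transcripts scaled for transcript length, that the authors made with kallisto 0.42.4, per the submitters' processing notes. kallisto assigns reads to transcript sequences by pseudoalignment and estimates a share for each transcript, divided by its length. TPM is relative within a library: a rise of a few abundant transcripts lowers all others. The transcript sequences, their assembly and any filter are not given in the sources used here. The identifiers have the form component, gene and isoform number that de novo assemblers write, and 145306 assembly genes were counted from them, of which 102049 had 1 transcript. The table holds 220713 transcripts with unique identifiers, none listed at 0 in all libraries. The columns sum to between 991754 and 998506, which is 0.149% to 0.825% short of the total that TPM has by definition. No gene names, coordinates or reference sequence were used here. For that reason the 27 lists of marker genes fixed beforehand were not applied and no list was tested, and transcripts are reported by identifier, at most 2 that rose and 2 that fell in a comparison.

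Read totals are not part of the table, and TPM keeps no absolute depth. Relative depth was read from low values: for transcripts alone in their component, ratios between libraries can cluster at ratios of small whole numbers. The most frequent ratio was taken as the value of 1 read relative to stage 26 replicate 1. This assumes that it stands for 1 read in both libraries, which was not checked. Between 4885 and 22571 transcripts were compared per library, and 16.0% to 20.8% of the ratios lay within 0.02 (log2) of 1:1, 1:2, 1:3, 2:1 or 3:1. No counts were inferred and no counting intervals were computed.

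Transcripts with at least 1 TPM in at least 2 of the 8 libraries were tested, which kept 151423 (68.6%). Values were transformed to log2(TPM + 1), so fold changes understate the change of low transcripts. A linear model with a mean for each stage was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in mean expression. The fit has 4 residual degrees of freedom and 3.01 prior degrees of freedom. All stages share 1 estimate of the spread per transcript, so a transcript at 0 in several libraries gets a small spread. Neighbouring stages were compared by two-sided moderated tests, and any change by the moderated F-test. Transcripts were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Nearly all calls also exceeded a 2-fold change (11173 of 11175 rises to stage 26). Named transcripts had an adjusted p under 0.05, a mean of at least 10 TPM over the 8 libraries, and both libraries of 1 stage above both of the other; the 2 largest rises and 2 largest falls on the log2 scale were taken. This rule, the tests and most alternatives were fixed before the data were examined. Replicates were compared before averaging, and the closest pair of libraries correlated at r = 0.858 across transcripts. Summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

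The fit was tested on simulated data, normal noise around the real means of the 151423 transcripts. Each transcript had 1 spread for all stages, its moderated estimate, and the values had no floor at 0. With no change, 0 transcripts were called in each of the 3 comparisons. With 50 transcripts of over 10 TPM changed at each of 4 sizes in the step from the 8-cell stage to stage 26, 0% of log2 changes of 1 and of 2 were called, 4% of changes of 4 and 90% of changes of 8, with 3 unchanged transcripts called. With 15000 changed transcripts in that step, 36.6% of changes of 2 and 92.7% of changes of 4 were called, and 3.98% of the calls were unchanged transcripts. In these simulated data the number of calls thus depended on how many transcripts changed as well as on the size of the change. Of the real rises to stage 26, 60.1% were listed at 0 in all egg and 8-cell libraries, where they show no spread. The simulated shares of changes called and of false calls may therefore not hold for the real fit.

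The alternatives covered the pseudocount, the filter on low values, 2 other scalings, a constant prior variance, a fit to the compared stages only, the replicate number as a block and each library left out in turn. After the data were seen, 4 were added: TPM summed per assembly gene, a covariate for the number of detected transcripts within a stage, a fit without stage 26 replicate 1 and tadpole replicate 2, and a fit without transcripts listed at 0 in all egg and 8-cell libraries. The planned sum over gene names did not apply, since the table pairs no transcript with one.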

Results

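Poly-A RNA was sequenced from whole unfertilized eggs, 8-cell embryos, embryos at stage 26 and swimming tadpoles of Hymenochirus boettgeri, the dwarf clawed frog, a small relative of Xenopus. Stage 26 is counted on the Nieuwkoop and Faber (NF) scale that is used for Xenopus; at that stage the tail bud has begun to form. Each of the 4 stages had 2 libraries, so the series had 8 libraries. Expression was given for 220713 transcripts, grouped by their identifiers into 145306 assembly genes, and no transcript was paired with a gene name. Transcripts are therefore described here as groups defined by their stage of expression, and by identifier for the few with the largest changes. The labels do not say whether the 2 libraries of a stage came from separate clutches, so p-values measure only the spread between these libraries, which may be technical.

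The mean number of transcripts at 1 TPM or more was lowest in eggs and highest in tadpoles, although the stage 26 and tadpole libraries overlapped. TPM is a share of all transcripts, scaled for length. At this minimum, eggs held 49056 ± 11179 transcripts and 8-cell embryos 63128 ± 4728 (mean ± SD, n = 2 each). Stage 26 embryos held 96185 ± 24970 and tadpoles 106260 ± 12210 (n = 2 each). At higher minimums this order weakened or turned. At 10 TPM or more, stage 26 replicate 2 (11147) and tadpole replicate 1 (12517) lay below both 8-cell libraries (12545 and 13181). At 100 TPM or more, the means were 1190 ± 197 in eggs, 1256.5 ± 53.0 in 8-cell embryos, 991.5 ± 235 at stage 26 and 913 ± 163 in tadpoles. The egg RNA was also the most concentrated in few transcripts. The 1000 most abundant transcripts held 58.0% ± 0.98 of the TPM in eggs and 48.0% ± 1.13 in 8-cell embryos (SD, n = 2). At stage 26 they held 40.6% ± 12.4 and in tadpoles 37.4% ± 7.16, and the values of these last stages overlapped. Stage 26 replicate 2 (49.3%) also lay above both 8-cell libraries (48.8% and 47.2%), so the lower mean at stage 26 rested on replicate 1 (31.8%). With 2 libraries against 2, a two-sided exact permutation test can give no p below 0.333, so these counts were compared by their spread alone. The libraries of 1 stage could differ widely: stage 26 replicate 1 held 113841 transcripts at 1 TPM or more and replicate 2 held 78528. Read totals were not given. Over low transcripts, 1 read was worth between 0.648 times (stage 26 replicate 2) and 1.14 times (8-cell replicate 1) its value in stage 26 replicate 1.

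**Figure D1:**
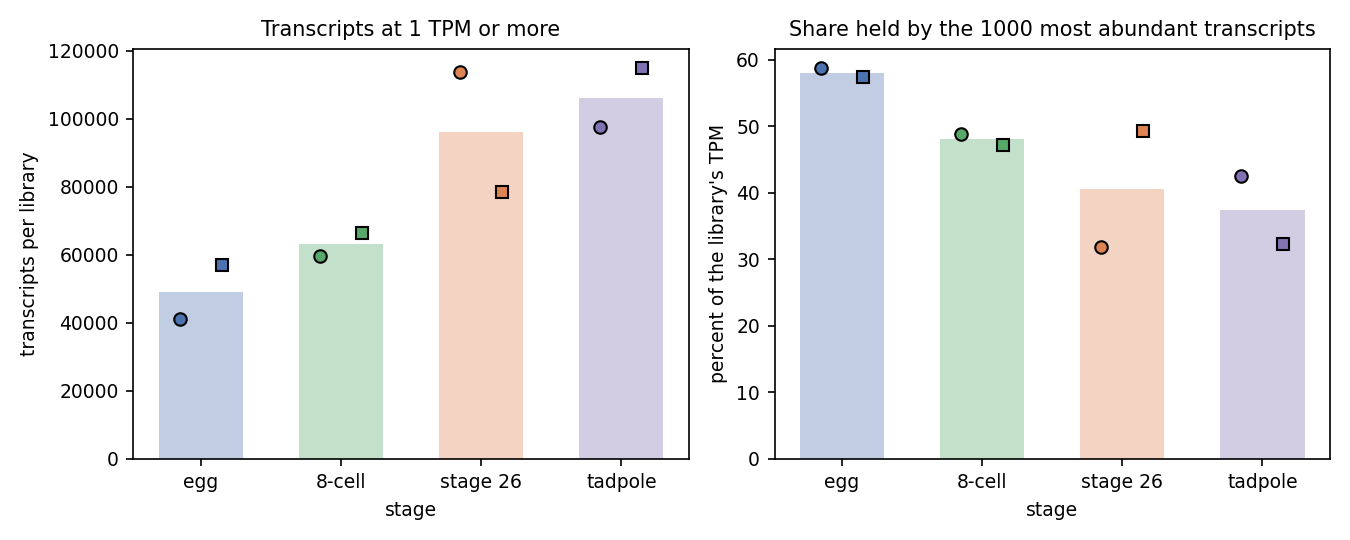
Left, number of transcripts at 1 TPM or more in each library; right, percent of each library's TPM held by its 1000 most abundant transcripts. Bars are stage means, circles replicate 1 and squares replicate 2; the means rise from 49056 transcripts in eggs to 106260 in tadpoles while the mean share falls from 58.0% to 37.4%. The stage 26 and tadpole libraries overlap in both plots, and stage 26 replicate 2 lies above both 8-cell libraries in the share.

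Most of the RNA in eggs and cleaving embryos came from transcripts that were also present later. Transcripts were grouped by their mean over the 4 egg and 8-cell libraries (early) and over the 4 stage 26 and tadpole libraries (late), with 1 TPM as the limit. There were 40806 early and late transcripts, 23106 early only and 77789 late only. The early and late group held 86.6% ± 5.43 of the TPM in eggs, 87.1% ± 1.96 at the 8-cell stage, 66.9% ± 13.4 at stage 26 and 56.1% ± 6.87 in tadpoles (SD, n = 2 each). Late-only transcripts held 28.9% ± 11.7 of the TPM at stage 26 and 39.2% ± 6.17 in tadpoles. Their libraries overlapped, from 20.7% to 37.2% at stage 26 and from 34.8% to 43.6% in tadpoles. Of the late-only transcripts, 41416 were listed at 0 in all 4 early libraries. Early-only transcripts held 11.01% ± 4.31 in eggs and 9.49% ± 1.70 in 8-cell embryos, and 7928 of them were listed at 0 in all 4 late libraries. With 5 TPM as the limit, the early and late group held 72.3% ± 3.16 in eggs and 70.0% ± 1.73 in 8-cell embryos. Early-only transcripts then held 16.7% ± 0.0996 and 15.6% ± 0.626, and 1402 of them were listed at 0 in all 4 late libraries. The groups were defined on the same libraries, so the contrast between early and late is set by the definition. The values within early and within late are not.

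**Figure D2:**
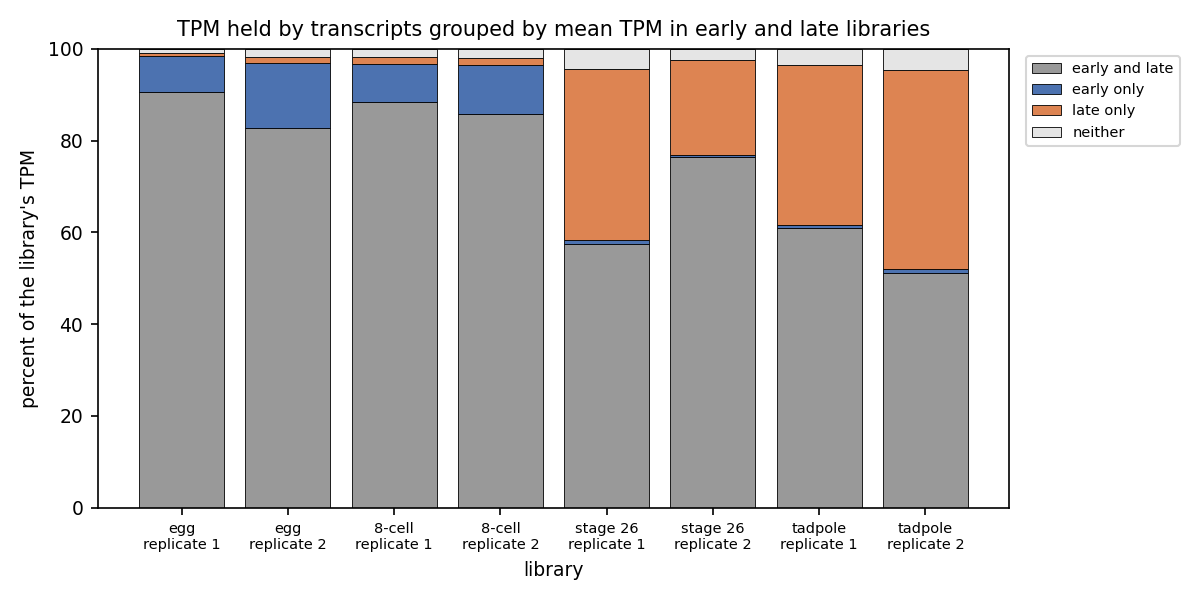
Percent of each library's TPM (vertical axis) held by transcripts with a mean of at least 1 TPM in the early libraries (egg and 8-cell), in the late libraries (stage 26 and tadpole), in both, or in neither; each bar is 1 library. Late-only transcripts hold 20.7% to 43.6% of the late libraries, and the bar of stage 26 replicate 2 differs most from those of the other late libraries.

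The first comparison, between 8-cell embryos and unfertilized eggs, covers fertilization and the first cleavages. No transcript passed the test in either direction. The abundant RNAs of the 2 stages were largely shared: an egg and an 8-cell library had 55 to 66 of their 100 most abundant transcripts in common. The 2 egg libraries shared 46 with each other and the 2 8-cell libraries shared 80. The correlation across transcripts showed the same order, with r = 0.623 between the egg libraries, 0.732 to 0.803 between an egg and an 8-cell library, and 0.858 between the 8-cell libraries. Transcripts are not independent replicates in these correlations. On both measures these 2 egg libraries differed from each other by more than either differed from an 8-cell library. This rests on 1 pair of egg libraries, with 69245 transcripts above 0 in replicate 1 and 104166 in replicate 2.

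The smallest adjusted p in this comparison was 0.172 (limma, two-sided moderated test on log2(TPM + 1), Benjamini-Hochberg adjusted over 151423 transcripts). At an unadjusted p under 0.05 there were 9933 transcripts, where chance gives 7571 if every tested transcript could vary. Transcripts listed at 0 in all egg and 8-cell libraries show no change here and cannot reach such a p with TPM as deposited. Without them 109255 were tested and 9185 had a p under 0.05, so 7571 overstates what chance gives. The count depended on the processing: it was 6103 with median-of-ratios scaling, 6865 with quantile normalization and 6873 in a fit to these 2 stages. Since 7571 is too high a baseline, these lower counts do not show whether an excess remains. Of the 9933, 9001 were higher in 8-cell embryos and 932 were higher in eggs. Both libraries of 1 stage lay above both of the other for 22.8% of transcripts, against 33.3% by chance with no ties. In simulated data with 50 transcripts of over 10 TPM changed at each of 4 sizes, this comparison called 0% of log2 changes of 2, 14% of changes of 4 and 90% of changes of 8. A small number of changes of up to 2 was therefore not detectable in such data, which have equal spread in all stages and no floor at 0. Quantile normalization moved the median change of all transcripts from 0 to -0.14.

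Between the 8-cell stage and stage 26, 11175 transcripts rose and 3971 fell, of 151423 tested. The median change was 2.56 among the transcripts that rose and -2.58 among those that fell, on the log2(TPM + 1) scale. The transcripts that rose held 0.464% ± 0.093 of the TPM at the 8-cell stage and 22.2% ± 1.66 at stage 26 (SD, n = 2). They held 0.548% ± 0.129 in eggs and 22.3% ± 0.366 in tadpoles. The egg and tadpole libraries are not independent of this choice of transcripts, since they enter the spread estimated for each. The transcripts that fell held 14.7% ± 1.23 at the 8-cell stage and 0.709% ± 0.258 at stage 26. In eggs they held 12.9% ± 1.91 and in tadpoles 0.634% ± 0.112, so neither group returned to its early share by the tadpole stage.

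Among the transcripts that rose, 6712 (60.1%) were listed at 0 in all 4 egg and 8-cell libraries. Both tadpole libraries lay above both 8-cell libraries for 8861 of the 11175, and 950 were listed at 0 in both tadpole libraries. Among the 3971 that fell, 1755 were listed at 0 in both stage 26 libraries. Both tadpole libraries lay below both 8-cell libraries for 3927 of them. In eggs the position was less uniform for these: both egg libraries lay above both stage 26 libraries for 2282 of the 3971 (57.5%), against 11159 of the 11175 with both egg libraries below. Chance gives 16.7% for 1 direction, but these counts reuse the 8-cell or stage 26 libraries on which the transcripts were chosen. The 2 egg counts are also not alike. For the 6712 rises listed at 0 in all early libraries, the egg libraries could not lie above stage 26. A fall is counted only if it was above 0 in both egg libraries, which had 69245 (replicate 1) and 104166 (replicate 2) transcripts above 0. The share of transcripts called rose with abundance, from 6.90% of those with a mean under 2 TPM over the 8 libraries to 23.9% of those at 100 TPM or more.

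The 2 largest rises among transcripts with a mean of at least 10 TPM belonged to 1 assembly gene. Transcript c80106_g1_i2 went from 0.688 ± 0.547 TPM at the 8-cell stage to 15910 ± 13990 TPM at stage 26, a log2 change of 12.89 (SE 0.88, adjusted p = 0.0127, limma). It was the most abundant transcript of stage 26 replicate 1 (25800 TPM) and of both tadpole libraries (10651 and 27924 TPM). Its neighbour c80106_g1_i1 went from 0.366 ± 0.517 to 2561 ± 1152 TPM, a log2 change of 10.85 (SE 0.65, adjusted p = 0.0127, limma). The 2 largest falls were of single transcripts whose level varied widely between the egg libraries. Transcript c46051_g1_i1 fell from 5068 ± 6157 to 0 and 1.04 TPM in the 2 stage 26 libraries, a log2 change of -10.83 (SE 1.95, adjusted p = 0.0263, limma). It was at 402 and 24179 TPM in the egg libraries. Transcript c152751_g1_i1 fell from 1137 ± 188 TPM to being listed at 0 in both stage 26 and both tadpole libraries (adjusted p = 0.0251, limma). It was at 2470 TPM in egg replicate 1 and 28.6 TPM in egg replicate 2. The 2 rises lost their call without 8-cell replicate 1 (adjusted p = 0.0700, limma) and without 8-cell replicate 2 (adjusted p = 0.109, limma). Their log2 changes were then 12.55 and 13.23 for c80106_g1_i2 and 10.45 and 11.25 for c80106_g1_i1. The 2 falls lost theirs without any 1 of the 8-cell, stage 26 or tadpole libraries, with adjusted p from 0.0565 to 0.175 (limma), and with a pseudocount of 5 (adjusted p = 0.0540 and 0.0556, limma). The log2 change of c46051_g1_i1 ranged from -12.69 to -8.97 without 1 of these libraries.

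The share of calls that rose depended on the scaling and on single libraries. It was 73.8% with TPM as deposited, 86.1% with median-of-ratios scaling (13616 rose, 2203 fell) and 57.1% with quantile normalization (5620 rose, 4225 fell). It was 59.4% without egg replicate 1 (6946 rose, 4747 fell), 58.9% without egg replicate 2 (6655 rose, 4638 fell), 86.9% without stage 26 replicate 1 (6566 rose, 990 fell) and 88.0% without stage 26 replicate 2 (23496 rose, 3207 fell). Median-of-ratios scaling moved the median change of all transcripts from 0.49 to 0.66 and quantile normalization moved it to 0.071. The count of 15146 calls was 3875 (2067 rose, 1808 fell) when transcripts listed at 0 in all egg and 8-cell libraries, which show no spread there, were left out, and 5207 with a pseudocount of 5. It was 0 without 8-cell replicate 1, 0 without 8-cell replicate 2 and 0 in a fit to these 2 stages alone, and it was 7556 without stage 26 replicate 1 and 26703 without stage 26 replicate 2. At an unadjusted p under 0.05 there were 46106 transcripts (32747 higher at stage 26), where chance gives 7571. It was 27014 without 8-cell replicate 1, 27993 without 8-cell replicate 2 and 46178 in the fit to 2 stages. Without transcripts listed at 0 in all egg and 8-cell libraries, 28174 of 109255 had an unadjusted p under 0.05 (15179 higher at stage 26, 12995 lower). The transcripts left out there get a small spread in the main fit, so 7571 is no firm baseline for the 46106. Both libraries of 1 stage lay above both of the other for 58.6% of transcripts, against 33.3% by chance with no ties.

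**Figure D3:**
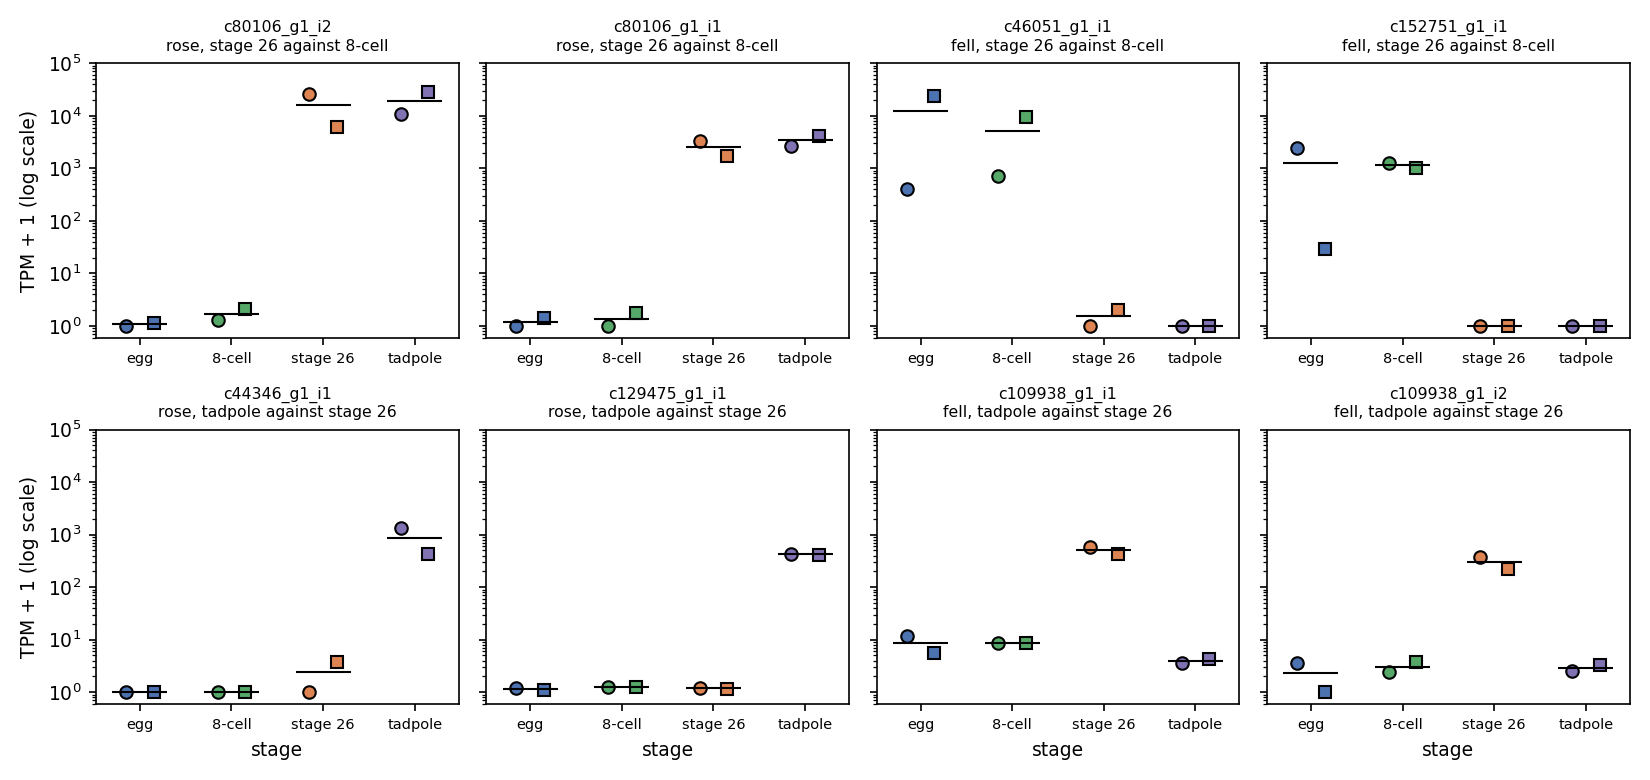
TPM + 1 on a log scale, by stage, for the 8 named transcripts. These are the 2 largest called rises and 2 largest called falls of each later step among transcripts that passed the rule for naming. Circles are replicate 1, squares replicate 2 and lines the stage means of TPM + 1. The upper panels show the step from the 8-cell stage to stage 26 and the lower panels the step from stage 26 to tadpoles, where c109938_g1_i1 is high only at stage 26 (500.8 TPM).

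Between stage 26 and the swimming tadpole, 6657 transcripts rose and 1677 fell. The transcripts that rose held 0.238% ± 0.017 of the TPM at stage 26 and 8.28% ± 1.13 in tadpoles (SD, n = 2). They had held 0.0649% ± 0.0020 in eggs and 0.0981% ± 0.0039 at the 8-cell stage, and 5291 of them (79.5%) were listed at 0 in all 4 egg and 8-cell libraries. The transcripts that fell held 1.82% ± 0.084 at stage 26 and 0.0965% ± 0.016 in tadpoles. Of these 1677, 1223 were also listed at 0 in all 4 egg and 8-cell libraries. Of transcripts with a mean under 2 TPM over the 8 libraries 6.76% were called, and of those at 100 TPM or more 3.53%.

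Among transcripts with a mean of at least 10 TPM, the largest rises were of ones at or close to 0 before the tadpole stage. Transcript c129475_g1_i1 went from 0.191 ± 0.042 to 423 ± 9.62 TPM, a log2 change of 8.48 (SE 0.45, adjusted p = 0.0201, limma). Transcript c44346_g1_i1 was listed at 0 in all egg and 8-cell libraries and went from 0 and 2.83 TPM at stage 26 to 1316 and 423 TPM in tadpoles (log2 change 8.58, SE 0.82, adjusted p = 0.0201, limma). The largest falls were again of 2 transcripts of 1 assembly gene, both high only at stage 26. Transcript c109938_g1_i1 fell from 500.8 ± 99.7 to 2.92 ± 0.433 TPM, a log2 change of -6.99 (SE 0.59, adjusted p = 0.0201, limma). It had been at 7.67 ± 0.0021 TPM at the 8-cell stage. Transcript c109938_g1_i2 fell from 302 ± 110 to 1.93 ± 0.512 TPM (log2 change -6.65, SE 0.73, adjusted p = 0.0201, limma). All 4 lost their call without any 1 of the egg or 8-cell libraries, with adjusted p from 0.0631 to 0.0962 (limma). Their log2 changes are the same there, since these libraries enter only the spread. The call of c109938_g1_i2 was also lost with a pseudocount of 0.1 (adjusted p = 0.0532, limma) and without transcripts listed at 0 in all egg and 8-cell libraries (adjusted p = 0.0515, limma).

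The 8334 calls of this step became 19 (18 rose, 1 fell) when transcripts listed at 0 in all egg and 8-cell libraries were left out, and 1842 with a minimum of 5 TPM in 2 libraries. Without stage 26 replicate 2, 5595 rose and 3264 fell (63.2% rose, against 79.9%). No transcript passed in limma without egg replicate 1, egg replicate 2, 8-cell replicate 1 or 8-cell replicate 2, each left out alone, and none in a fit to the stage 26 and tadpole libraries alone. At an unadjusted p under 0.05 there were 24552 transcripts (17123 higher in tadpoles), where chance gives 7571, 17409 in the fit to these 4 libraries, and 20718 to 23528 without an egg or 8-cell library. Without transcripts listed at 0 in all egg and 8-cell libraries, 9248 of 109255 had an unadjusted p under 0.05 (5687 higher in tadpoles, 3561 lower). The transcripts left out there get a small spread in the main fit, so 7571 is no firm baseline for the 24552. Median-of-ratios scaling moved the median change of all transcripts from 0 to 0.14. Both libraries of 1 stage lay above both of the other for 34.5% of transcripts, against 33.3% by chance with no ties. Transcripts tied between the stages cannot be counted, and the filter on low values was not allowed for, so 33.3% is no exact baseline.

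The calls of the 2 later steps overlapped mostly in 1 pattern. Of the transcripts that rose from the 8-cell stage to stage 26, 1563 were also among the 1677 that fell by the tadpole stage, and 98 were among those that rose further. Only 15 transcripts fell and then rose, and 4 fell in both steps. Independent lists of these sizes would share 124 for a rise and then a fall and 491 for 2 rises. The 2 steps share the stage 26 libraries, which by itself favours opposite directions. In 20 simulated sets with no change, lists of the real lengths taken by the smallest p shared a mean of 872 transcripts (824 to 917) for a rise and then a fall and 1319 for a fall and then a rise. For 2 rises they shared a mean of 77.0 (58 to 89), below the 98 observed, and for 2 falls 7.5 (2 to 12). The simulated values had no floor at 0. Of the 1677 falls, 1223 were listed at 0 in all egg and 8-cell libraries and 907 in both tadpole libraries. For each of the 1223, the earlier rise from 0 was at least as large as the fall, with the same spread. The rises also had a less strict limit, since more transcripts were called in that step. All 1223 were therefore bound to be among the rises, which sets most of the 1563 in advance. With 1319 simulated against 15 observed for a fall and then a rise, the simulated sets are no baseline for the observed counts. Beyond the 1223, more of the 1563 may also come from the shared libraries, which are too few to be split. The falls of the later step numbered 1 without transcripts listed at 0 in all egg and 8-cell libraries. They numbered 0 in limma without egg replicate 1, egg replicate 2, 8-cell replicate 1 or 8-cell replicate 2, and 0 in the fit to 2 stages, so no overlap with falls is left in these. At an unadjusted p under 0.05, 5965 to 7433 transcripts were lower in tadpoles without 1 of these libraries and 5678 in the fit to 2 stages.

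Over all 4 stages, 33918 of the 151423 transcripts (22.4%) changed in the moderated F-test of limma at an adjusted p under 0.05. The early and late libraries were the main division of the series. The first principal component held 53.0% of the variance and separated the egg and 8-cell libraries from the rest. The late libraries divided by stage in some measures and not in others. The second component (12.2% of the variance) parted stage 26 from tadpole libraries. Spearman correlations across transcripts were 0.535 and 0.579 within a stage and 0.384 to 0.468 between the stages. Pearson r was 0.653 within stage 26 and 0.698 within tadpoles, and between the stages it was 0.515 to 0.654, the highest being stage 26 replicate 2 with tadpole replicate 1. The most abundant transcripts were shared more across than within these stages in 2 pairs. Stage 26 replicate 1 shared 63 of its 100 most abundant transcripts with tadpole replicate 2, and stage 26 replicate 2 shared 62 with tadpole replicate 1. The 2 libraries of stage 26 shared 48, as did the 2 tadpole libraries. The F-test called 12514 transcripts without egg replicate 1 and 13697 without egg replicate 2. It called 0 without 8-cell replicate 1 and 0 without 8-cell replicate 2, where 42565 and 43381 had an unadjusted p under 0.05.

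**Figure D4:**
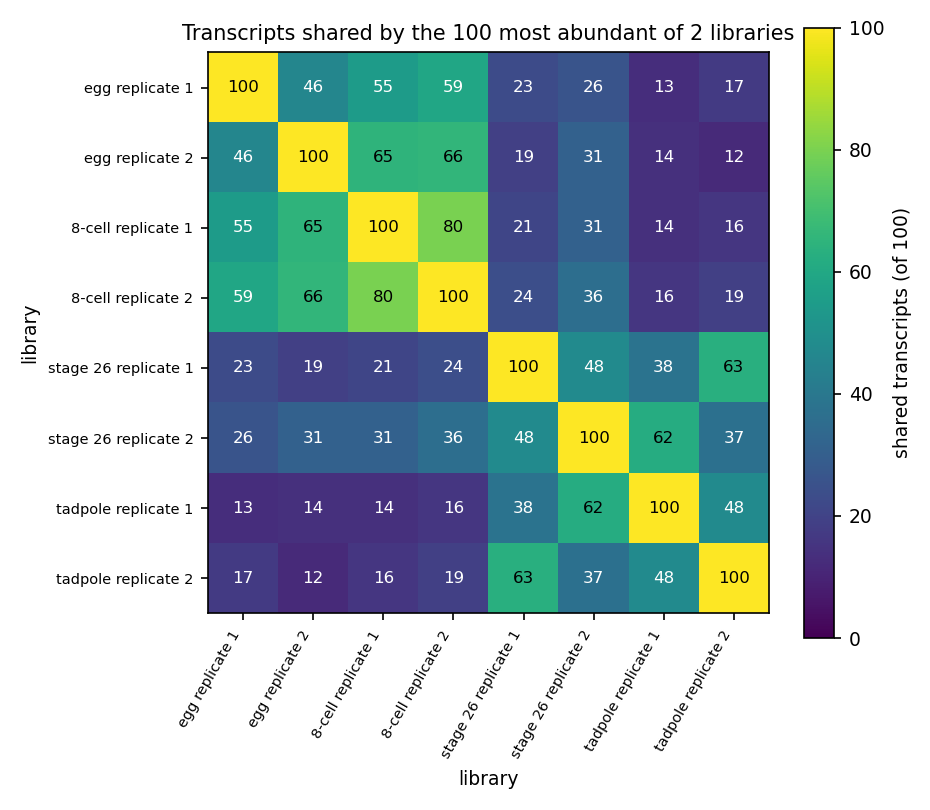
Number of transcripts shared between the 100 most abundant of each pair of libraries; rows and columns are the 8 libraries and the colour runs from 0 to 100 shared transcripts. The 8-cell libraries share 80, and 2 pairs of late libraries share more across stages (63 and 62) than the pairs within a stage (48 and 48), while the other 2 pairs across stages share fewer (38 and 37).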

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

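Of the alternatives, 4 were chosen after seeing the data: the sum per assembly gene, the covariate for detected transcripts, the fit without stage 26 replicate 1 and tadpole replicate 2, and the fit without transcripts listed at 0 in all egg and 8-cell libraries. The comparison of 8-cell embryos with eggs called 0 transcripts under every alternative in limma, except 10 without stage 26 replicate 1 and tadpole replicate 2. The 15146 calls between the 8-cell stage and stage 26 became 29988 with a pseudocount of 0.1, 5207 with a pseudocount of 5, 8816 with no filter and 9845 with quantile normalization. The 8334 calls between stage 26 and tadpole became 5514 with no filter, 1842 with at least 5 TPM in 2 libraries, 3781 with quantile normalization and 3216 with a constant prior variance. The 33918 calls of the F-test became 17586 with a pseudocount of 5, 16573 with at least 5 TPM in 2 libraries (fewer transcripts tested) and 17426 with quantile normalization. A fit to the 2 compared stages alone, with fewer libraries, called 0 in each comparison, where 46178 (stage 26) and 17409 (tadpole) had an unadjusted p under 0.05. Leaving out each library in turn gave 0 to 26703 calls at stage 26, 0 to 11860 in tadpoles and 0 to 45713 in the F-test. A stage left with 1 library is assumed to vary like the others. The calls at stage 26 were 0 without either 8-cell library, 7556 without stage 26 replicate 1 and 26703 without stage 26 replicate 2. Those in tadpoles were 0 without any 1 of the egg or 8-cell libraries, and those of the F-test were 0 without either 8-cell library, 12514 without egg replicate 1 and 13697 without egg replicate 2. Leaving out transcripts listed at 0 in all egg and 8-cell libraries gave 3875, 19 and 6697 calls at stage 26, in tadpoles and in the F-test, and the covariate gave 5123 in tadpoles. Leaving out both stage 26 replicate 1 and tadpole replicate 2 gave 43338, 47273 and 57279. The spread then comes from egg and 8-cell libraries alone and is 0 for transcripts at 0 there, which inflates these counts. Without an egg or 8-cell library, the log2 changes from stage 26 to tadpole stay the same. Only the estimated spread and its degrees of freedom can therefore lower those calls. The cause of the other shifts was not tested. The labels number the libraries 1 and 2 in each stage but say nothing of pairing. Deviations of same-numbered libraries correlated at 0.151 between egg and 8-cell, -0.035 between 8-cell and stage 26 and -0.251 between stage 26 and tadpole. The last value is negative because differently numbered stage 26 and tadpole libraries deviated alike. These values do not settle whether any libraries were paired. With the replicate block, which leaves 1 residual degree of freedom less, 0 transcripts were called in each comparison and 11142 by the F-test, and 41647 (stage 26) and 22059 (tadpole) had an unadjusted p under 0.05. The mean number of transcripts per stage (egg, 8-cell, stage 26, tadpole) was 80662, 105491, 155148 and 164480 at 0.1 TPM or more, 18945, 23487, 29231 and 31006 at 5 TPM, and 10651, 12863, 13583 and 14074 at 10 TPM. With median-of-ratios scaling it was 53228 at the 8-cell stage and 118989 in tadpoles. For the 8 named changes, 104 of 159 alternative values stayed called, 55 lost their call and 0 changed sign. Absolute depth is unknown, so a transcript listed at 0 is not shown to be absent.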

Other observations

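The tests on swapped labels and on the value of 1 read were chosen after the results they bear on were seen; the tests of abundant transcripts, of developmental age, of scaling and of egg replicate 1 were fixed before, except that counts per direction were weighed for egg replicate 1 only afterwards.

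Called transcripts of 1 assembly gene mostly had the same direction between the 8-cell stage and stage 26. Of 1182 assembly genes with at least 2 called transcripts, 1143 had all of them in 1 direction and 39 had some that rose and some that fell. Shuffling the directions among these transcripts gave a mean of 434 genes with both directions over 1000 shuffles, and never fewer than 403. The shuffles treat these transcripts as independent, which transcripts of 1 assembly gene need not be, since they can share sequence and reads. The difference from the shuffles therefore does not show separate transcripts changing together. Summing TPM over each of the 39 genes left 3 with a called total, 1 that rose and 2 that fell, and the median absolute log2 change of the totals was 0.96 (quartiles 0.40 and 1.58). The egg libraries also held more of their TPM in very few transcripts than the later stages: the 10 most abundant held 10.002% and 13.5% in the egg libraries and 4.57% to 6.95% in the other libraries.

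Stage 26 replicate 1 held 1.45 times as many transcripts at 1 TPM or more as replicate 2, and tadpole replicate 2 held 1.18 times as many as tadpole replicate 1, while for transcripts above 0 the ratios were 1.077 and 1.007; these same 2 libraries also shared 63 of their 100 most abundant transcripts. Deeper sequencing of them is argued against only if the most frequent ratio of low values stands for 1 read in both libraries, which was not checked. On that reading, 1 read was worth 1.16 times as much TPM as in the other tadpole library. It was worth 1.54 times as much as in the other stage 26 library. A swap of labels between the stages is argued against as well: 220 of 12715 transcripts parted the labelled stages by at least 4 on the log2 scale, and 5 parted the crossed pairs. A smaller share of TPM in abundant transcripts may account for part of both differences. Without the 1000 most abundant transcripts the ratio fell from 1.18 to 1.06 in tadpoles and from 1.45 to 1.22 at stage 26. The limit set beforehand was met only in tadpoles, where the ratio was lower at the start. TPM is a share, so a lower share at the top and more transcripts at 1 TPM are not independent. Whether stage 26 replicate 1 was further along in development stays open (r = 0.091 across 5675 transcripts, between the limits set beforehand), as does a shared library batch or clutch, which the labels do not give and which was not tested.

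Of the 9933 transcripts with an unadjusted p under 0.05 between egg and 8-cell embryos, 90.6% were higher in 8-cell embryos, although none was called. Without egg replicate 1, which had the fewest detected transcripts, 59.5% were higher, but the share fell mainly because transcripts lower in 8-cell embryos rose from 932 to 4955, while the higher ones went from 9001 to 7269. Whether that library made the excess therefore stays open, and without egg replicate 2 the share was 78.9% (12807 higher, 3434 lower). For egg replicate 1 the share did meet the limit set beforehand for that library as the cause. The question is left open only by the counts per direction, which were weighed afterwards. Scaling stays open: with median-of-ratios scaling 75.6% were higher (4614 against 1489 lower), between the limits set beforehand, and with quantile normalization 73.2%. A difference between the stages themselves, such as longer poly-A tails after fertilization, stays open and was not tested.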
